A study of Mus musculus with 15 samples.

How the data were processed

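Total RNA from 10 Rb/p53 tumours, 3 Rb/p53/p130 tumours and 2 normal lungs of mice was isolated with Trizol, amplified with a RiboAmp kit in a pair of rounds and hybridised to Affymetrix mouse whole-genome arrays, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array, made with RMA (background correction, normalisation between arrays and summary of probes), per the submitters' processing notes, which give no version. Values ran from 3.11 to 15.2, and the sorted values of any 2 arrays differed by at most 0.32 (median 0.11), as measured on the deposited table. RMA over all arrays sets their distributions nearly equal, so a change shared by most genes would not be seen, and amplification shortens RNA towards its 3' end, which can move probe sets that lie far from it. No scan date, slide or batch is given in the sources used here. No 2 arrays held identical values.

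Of 45101 probe sets, 64 controls were left out and 45037 tested. The probe table gave 1 gene symbol for 34945, several for 932 and none for 9160, and of those with 1 symbol 34741 were matched by gene ID to the RefSeq table of assembly GRCm38.p6, used for names and for the order of neighbouring genes. A gene was counted through its probe set with the highest mean over all arrays, which gave 18193 genes. Groups came from the sample labels.

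Models were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the deposited log2 values, all 3 groups in 1 fit because 2 normal lungs give little estimate of their own spread. P-values were adjusted by Benjamini-Hochberg over probe sets and called at 0.05. Errors of changes are limma's moderated inputs, the SE of the log2 difference, and errors of levels are SD. Gene lists, 33 with 574 entries of which 530 were measured, were written before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Fry tests a list's own genes and does not compare it with other genes. For Rb/p53 tumours against normal lung camera called 8 lists higher and 13 lower, of which 4 held with an estimated correlation; for Rb/p53/p130 tumours against normal lung 7 and 12, of which 3 held; and between tumour genotypes 6 and 5, of which 0 held. Fry called 23, 21 and 0 lists in these comparisons.

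A fixed rule selected the targeted genes, a fixed panel of 36 genes of which 33 were measured, the 6 highest rises and 6 deepest falls per comparison among called genes whose arrays did not overlap, and up to 3 called members of each list with the highest absolute change, or the member with the smallest p where none was called. The text names the measured genes of all but the last kind in at least 1 comparison, and only some of the list members. A gene outside this rule is said to be chosen after its values were seen, apart from the liver genes and the neighbours of Mycn and E2f1 given near the end. Folds whose lower group lay at or below the highest lower quartile of the arrays are given as lower bounds. Agreement of the 2 comparisons with normal lung was set against 100 simulations of unchanged groups sharing the 2 lungs.

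The fit was tested on simulated data of 45037 probe sets with 200 changed genes. For Rb/p53 tumours against normal lung 4.55% of changes of 0.5 on the log2 scale, 61.2% of changes of 1 and 76.1% of changes of 2 were recovered. For Rb/p53/p130 tumours against normal lung the shares were 0%, 34.3% and 76.1%, and between tumour genotypes 9.09%, 56.7% and 98.5%. Against normal lung these simulations made 101 and 75 calls, where the data gave 14464 and 11287 called probe sets. The adjustment is stricter with so few changes, so these shares do not carry over to the comparisons with normal lung. Between genotypes the simulation made 116 calls and the data 95.

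Alternatives left out each array in turn, normalised again by quantiles, centred arrays on their medians, kept only probe sets brighter than the median, fitted the compared groups alone, weighted arrays, used a trended and robust prior, added the Gapdh control difference as a covariate, averaged each gene's probe sets, left out probe sets with suffixes _s, _x and _a, blocked on the array number, required a change of 1, and used an exact rank-sum test. Covariates for Xist and for the actin controls, a fit without the pair of tumours highest in the hepatocyte list, and the agreement with each genotype set against a different normal lung, were chosen after seeing the data. Correlations across tumours used 100000 permutations, intervals of medians 2000 bootstrap draws at 95%, and splits of the tumours 100 draws of 286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Trp53 and Calca, and 44 list entries in all, were not analysed here.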

Results

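Gene expression was measured on Affymetrix mouse whole-genome arrays in 15 samples of mouse lung, to profile a mouse model of small cell lung cancer (SCLC, an aggressive neuroendocrine lung tumour) and to ask how closely it resembles the human disease. Tumours were started by Cre recombinase, delivered to the airways by an adenovirus, which deletes floxed alleles in the cells it enters. The groups were 10 tumours lacking Rb and p53, taken 8 to 12 months after infection, 3 tumours lacking Rb, p53 and the Rb relative p130, taken at 6 months, and 2 normal lungs. Human tumours were not analysed here. The labels do not say that the arrays of a group came from separate mice, so p-values measure only the spread between these samples. Array medians lay between 6.58 and 6.68 on the log2 scale, and the number of arrays limits the precision. The 2 normal lungs correlated with each other at r = 0.983 across probe sets, and with the Rb/p53 tumours at r = 0.842 to 0.909. The first principal component held 50.7% of the variance and placed both normal lungs (189 and 188) apart from all 13 tumours (-69.6 to 3.26).

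The targeted genes were read first. Rb1, read from its brightest probe set, had a log2 level of 10.20 ± 0.20 (SD, n = 2) in normal lung, 11.50 ± 0.41 (SD, n = 10) in Rb/p53 tumours and 11.76 ± 0.12 (SD, n = 3) in Rb/p53/p130 tumours. The signal was higher in both tumour groups (limma adjusted p = 0.00154 and 0.00192). Rbl2, which encodes p130, stood at 9.57 ± 0.01 in normal lung, 8.66 ± 0.42 in Rb/p53 tumours and 8.61 ± 0.21 in Rb/p53/p130 tumours. This probe set was called lower than in normal lung in both tumour groups (limma adjusted p = 0.0178 and 0.0391). By it the tumour genotypes differed by -0.05 ± 0.23 (SE, limma adjusted p = 0.972). A second probe set of Rbl2 was called against normal lung in neither group (limma adjusted p = 0.107 and 0.351). Where these probe sets lie relative to the deleted exons is not given in the sources used here, so neither gene checks the genotype labels. Trp53 was not analysed here, nor was Calca of the neuroendocrine genes.

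The comparison of Rb/p53 tumours with normal lung asked what the tumours express that the lung does not. Neuroendocrine genes were far higher in the tumours. Snap25, a vesicle fusion protein of neurons, was higher by at least 166-fold (log2 change 7.38 ± 0.30, adjusted p = 6.03e-10) in limma (10 against 2 arrays, errors are SE). Insm1, a neuroendocrine transcription factor, was higher by at least 141-fold (log2 change 7.14 ± 0.40, adjusted p = 8.75e-09) and the secretory granule protein Chga by 82.5-fold (log2 change 6.37 ± 0.51, adjusted p = 2.69e-07). Folds are lower bounds (at least) where the lower group lay at or below the highest lower quartile of the arrays (5.04867), which is not shown to be above background. Genes of the dividing cell were higher as well, among them Cdk1 by 41.2-fold (log2 change 5.36 ± 0.19) and Mki67 by 26.1-fold (log2 change 4.71 ± 0.27). Genes of the resident lung were lower, including the endothelial gene Tmem100 by 62.4-fold (log2 change -5.96 ± 0.91) and the ciliary gene Ccdc113 by at least 21.6-fold (log2 change -4.43 ± 0.22).

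Of the neuroendocrine list, 21 of 27 were higher and 1 lower (21 and 2 adjusted over the list alone, camera adjusted p = 3.80e-15, adjusted p = 0.0239 with an estimated correlation). The median log2 change of the list was 4.59. Scg2 (at least 169-fold) and Scg5 (at least 144-fold), both of secretory granules, were among its highest. Uchl1, a neuronal ubiquitin hydrolase, was 43.0-fold higher and the adhesion molecule Ncam1 24.2-fold higher. The Notch ligand Dll3 was higher by 4.53 ± 0.27 in log2 and the vesicle protein Syp by 2.85 ± 0.30. The bombesin-like peptide Grp had a log2 change of 1.92 ± 1.05 (limma adjusted p = 0.189) and Neurod1 of 0.33 ± 0.40 (adjusted p = 0.586). The amine-forming enzyme Ddc (98.3-fold), also of the list, and the transcription factor St18 (at least 111-fold), outside it, were among the 6 genes with the highest measured rise. For synapse and axon genes, 18 of 27 were higher (22 adjusted over the list alone, camera adjusted p = 8.04e-09, adjusted p = 0.0381 with an estimated correlation). Kif5c (27.0-fold), a motor of axonal transport, and Cplx2 (21.3-fold) led them.

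Among genes linked to SCLC, 11 of 20 were higher (11 and 1 adjusted over the list alone, camera adjusted p = 0.000590, adjusted p = 0.0361 with an estimated correlation). Crmp1 was 32.4-fold and Hmgb2 8.46-fold higher. Mycl, a MYC family oncogene, was 6.51-fold (log2 change 2.70 ± 0.84, adjusted p = 0.0225) higher and Sox2 2.43-fold (log2 change 1.28 ± 0.44, adjusted p = 0.0362) higher in limma. Mycn had a log2 change of 1.66 ± 1.10 (limma adjusted p = 0.284), and its SD of 1.80 among Rb/p53 tumours came with 1 tumour, number 7, at 12.19. Myc (0.03 ± 0.31), Nfib (-0.22 ± 0.35) and Nkx2-1 (0.13 ± 0.17) did not pass the test. Of tuft-like SCLC genes, 1 of 9 was higher (1 adjusted over the list alone, camera adjusted p = 0.709), and their factor Pou2f3 had a log2 change of -0.15 ± 0.15. Of Notch and non-neuroendocrine genes, 1 of 20 was higher and 15 lower (1 and 16 adjusted over the list alone, camera adjusted p = 2.65e-05, adjusted p = 0.131 with an estimated correlation). The receptor Notch1 was 7.98-fold lower, the co-activator Yap1 7.33-fold, the neuronal gene repressor Rest 3.44-fold and Hes1 3.88-fold lower. In the Hedgehog pathway, 1 of 10 was higher and 7 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.00877, adjusted p = 0.0752 with an estimated correlation), with Shh 11.2-fold and Smo 6.49-fold lower. Notch and Hedgehog genes were read in bulk tissue, in which markers of resident lung cells were lower too. Their falls cannot be told apart from a smaller share of lung cells in the samples.

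G2/M genes and E2F targets were higher nearly throughout. In the G2/M list 29 of 29 were higher (29 adjusted over the list alone, camera adjusted p = 6.72e-26, adjusted p = 0.0752 with an estimated correlation), with a median log2 change of 4.43. Ccnb2 (41.8-fold), Ube2c (41.3-fold) and Top2a (27.4-fold) belonged to it. Of E2F targets of G1/S, 30 of 31 were higher (30 adjusted over the list alone, camera adjusted p = 1.71e-24, adjusted p = 0.0752 with an estimated correlation). The replication helicase subunit Mcm6 was 21.9-fold higher. Of Rb family, E2F and cyclin genes, 16 of 28 were higher and 5 lower (17 and 5 adjusted over the list alone, camera adjusted p = 0.000590, adjusted p = 0.0774 with an estimated correlation). Cdkn2a, which encodes p16 and p19Arf, was 49.5-fold (log2 change 5.63 ± 0.28, adjusted p = 3.07e-09) higher. Ccne1 was 2.83-fold, Ccne2 28.1-fold, E2f8 18.2-fold and the Rb relative Rbl1 2.29-fold higher. E2f1 was 3.82-fold higher (limma adjusted p = 0.0151), with tumour 8 at 11.73 and the other 9 averaging 8.99 ± 0.26 (SD). Of homologous recombination and Fanconi genes, 11 of 15 were higher (12 adjusted over the list alone, camera adjusted p = 3.06e-08, adjusted p = 0.131 with an estimated correlation). Rad51ap1 (at least 32.2-fold), Chek1 (17.4-fold) and Brca1 (14.4-fold), all of DNA repair, led them. Of p53 targets, 2 of 22 were higher and 9 lower (3 and 9 adjusted over the list alone, camera adjusted p = 0.164). Pmaip1, which promotes apoptosis, was 9.04-fold lower, whereas the spindle protein Ckap2 was higher by 4.53 ± 0.24 in log2 and the cell cycle inhibitor Cdkn1a by 1.01 ± 0.24. Mdm2 had a log2 change of -0.05 ± 0.15 (limma adjusted p = 0.840).

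Markers of the resident lung cells were lower. In the endothelial list 21 of 22 were lower (21 adjusted over the list alone, camera adjusted p = 1.99e-11, adjusted p = 0.150 with an estimated correlation). Car4 of capillaries was 35.9-fold and Pecam1 9.58-fold lower. Among ciliated cell genes 14 of 19 were lower (14 adjusted over the list alone, camera adjusted p = 1.75e-10, adjusted p = 0.0381 with an estimated correlation). Among alveolar type 1 genes 1 of 14 was higher and 13 lower (1 and 13 adjusted over the list alone, camera adjusted p = 8.52e-05, adjusted p = 0.259 with an estimated correlation). Among alveolar type 2 genes 9 of 15 were lower (11 adjusted over the list alone, camera adjusted p = 0.00609, adjusted p = 0.504 with an estimated correlation). Their mean ran from 8.67 to 11.73 among the Rb/p53 tumours. Sftpc, the surfactant gene of these cells, remained at 13.36 ± 1.19 (SD) against 14.88 ± 0.03 in normal lung (limma adjusted p = 0.156). Of club and secretory genes, 6 of 13 were lower (7 adjusted over the list alone, camera adjusted p = 0.00960, adjusted p = 0.394 with an estimated correlation). Cyp4b1, a club cell oxidase, was 24.4-fold lower. The signal of Scgb1a1 lay at the top of the normal lung arrays (15.195), so its change was not measured. Of fibroblast and smooth muscle genes, 15 of 22 were lower (16 adjusted over the list alone, camera adjusted p = 7.72e-07, adjusted p = 0.127 with an estimated correlation), with Cnn1 19.2-fold lower. The collagen gene Col1a1 had a log2 change of 0.05 ± 0.47 (limma adjusted p = 0.956). Of mesothelial genes, 6 of 6 were lower (6 adjusted over the list alone, camera adjusted p = 2.65e-05, adjusted p = 0.0752 with an estimated correlation). Of cardiac muscle genes, which line pulmonary veins in mice, 13 of 15 were lower (1 and 13 adjusted over the list alone, camera adjusted p = 5.23e-08, adjusted p = 0.0752 with an estimated correlation). Myh6, a heart myosin, was 91.7-fold (log2 change -6.52 ± 0.81) lower and Myl7, an atrial light chain, 43.1-fold (log2 change -5.43 ± 0.73) lower. The deepest falls also held the carbonic anhydrase Car3 (109-fold), the sulphotransferase Sult1d1 (at least 61.4-fold) and the oxidase Cyp1a1 (58.9-fold).

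Immune markers were lower in part. Of B and plasma cell genes, 13 of 15 were lower (13 adjusted over the list alone, camera adjusted p = 2.65e-05, adjusted p = 0.244 with an estimated correlation). Of T and NK cell genes, 9 of 19 were lower (9 adjusted over the list alone, camera adjusted p = 0.000447, adjusted p = 0.280 with an estimated correlation), with Klrd1 of NK cells at least 7.73-fold lower. Of macrophage and dendritic genes, 5 of 19 were higher and 5 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.709). Complement C1qb was 4.53-fold and Cd68 2.74-fold higher, whereas the scavenger receptor Cd163 was at least 5.98-fold and Siglecf, of alveolar macrophages, 5.00-fold lower. In the hypoxia and glycolysis list 8 of 16 were higher and 2 lower (10 and 4 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.259 with an estimated correlation). Egln3, an oxygen sensor, was 23.7-fold higher and the angiogenic factor Vegfa 3.56-fold lower. Of adipocyte genes, 4 of 7 were lower (4 adjusted over the list alone, camera adjusted p = 0.00847, adjusted p = 0.131 with an estimated correlation). The remaining lists did not pass camera. For neutrophils 2 of 10 were lower (2 adjusted over the list alone, camera adjusted p = 0.136). For thymocytes 1 of 6 was lower (1 adjusted over the list alone, camera adjusted p = 0.886). For hepatocytes 1 of 10 was lower (1 adjusted over the list alone, camera adjusted p = 0.984). For erythroid cells 2 of 6 were lower (2 adjusted over the list alone, camera adjusted p = 0.182). In MHC class I presentation 1 of 12 was lower (0 adjusted over the list alone, camera adjusted p = 0.868). In MHC class II presentation 1 of 7 was lower (0 adjusted over the list alone, camera adjusted p = 0.212). In the interferon response 1 of 17 was higher (1 adjusted over the list alone, camera adjusted p = 0.358). Of immediate early genes 4 of 18 were lower (4 adjusted over the list alone, camera adjusted p = 0.436). Of sex-linked genes 0 of 4 passed in limma (0 adjusted over the list alone, camera adjusted p = 0.947).

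**Figure D1:**
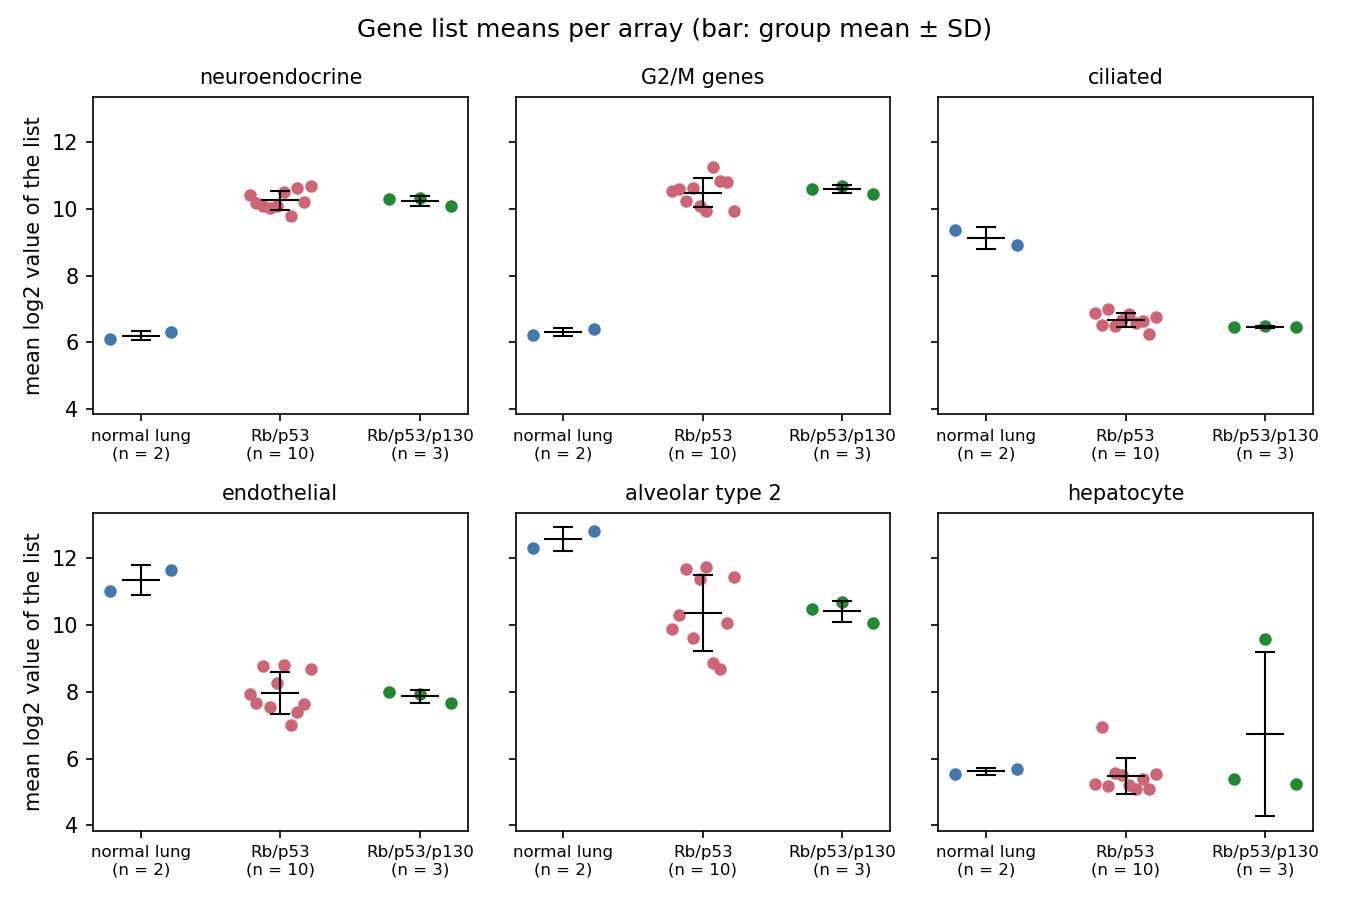
Mean log2 value of 6 gene lists (vertical axes) on each array, for normal lung (n = 2), Rb/p53 tumours (n = 10) and Rb/p53/p130 tumours (n = 3); points are arrays and black bars are group means ± SD. The neuroendocrine mean is 6.20 ± 0.13 in normal lung and 10.26 ± 0.29 in Rb/p53 tumours, and 1 Rb/p53/p130 tumour stands at 9.57 in the hepatocyte list.

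Across the array, 7058 of 18193 genes passed the threshold in limma with Benjamini-Hochberg adjustment, 3328 higher and 3730 lower in Rb/p53 tumours, and 4179 of them changed by at least 1 on the log2 scale. Expression did not overlap between the groups in 38.4% of genes, where chance gives 3.03%. With the 3' to 5' difference of the Gapdh controls, a measure of RNA integrity that was 0.72 and 0.88 in normal lung and -0.07 to 0.36 in tumours, as a covariate, 1106 genes passed. With that of actin, chosen after the data were seen, 4472 passed. The Gapdh covariate ended the calls of 4 lists, alveolar type 2, T and NK cell, B and plasma cell, and hypoxia and glycolysis. Among the genes given above it ended the calls of C1qb, Car3, Car4, Ccne1, Cd163, Cd68, Cdkn1a, Cyp4b1, E2f1, Hes1, Hmgb2, Mycl, Myh6, Myl7, Notch1, Pecam1, Rb1, Rbl1, Rbl2, Rest, Scg2, Shh, Siglecf, Smo, Sox2, Syp, Tmem100, Vegfa and Yap1. The covariate differs between lung and tumour, so a lost call need not mean a smaller change. With it the log2 change was no smaller for Mycl (4.37), Shh (-4.46), Rb1 (1.33) and several more of these genes, among them Car3, Hes1, Pecam1, Smo and Yap1. It was smaller for others, such as C1qb (0.19) and Cdkn1a (0.52). The count was 3891 with the array number as a block, a contrast that rests on tumours 1 and 2 and the 2 lungs. It was 0 by an exact rank-sum test (6994 at an unadjusted p under 0.05), whose smallest adjusted p was 0.0950. With 10 against 2 arrays the p of that rank-sum test cannot go below 0.0303 before adjustment, which limits what it can call.

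The Rb/p53/p130 tumours were compared with the same 2 normal lungs. Neuroendocrine genes were again higher, with Snap25 by at least 183-fold (log2 change 7.52 ± 0.35, adjusted p = 4.54e-09) and Insm1 by at least 163-fold (log2 change 7.35 ± 0.47, adjusted p = 5.64e-08) in limma (3 against 2 arrays, errors are SE). The secreted protease Klk1 was 149-fold (log2 change 7.22 ± 1.52, adjusted p = 0.00262) higher and the neuronal RNA-binding protein Elavl2 at least 146-fold (log2 change 7.19 ± 1.48, adjusted p = 0.00220) higher. Tmem100 was 56.5-fold (log2 change -5.82 ± 1.08) lower, Myh6 106-fold (log2 change -6.72 ± 0.95) lower and the chemokine Ppbp at least 48.7-fold (log2 change -5.61 ± 0.63) lower. The oxidase Cyp1a1 (at least 73.0-fold), the atrial light chain Myl7 (67.1-fold) and the matrix protein Pcolce2 (59.0-fold) were lower as well, while Scg2 (at least 166-fold) and St18 (at least 139-fold) were higher.

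Of the neuroendocrine genes 21 of 27 were higher and 2 lower (22 and 2 adjusted over the list alone, camera adjusted p = 2.68e-16, adjusted p = 0.0177 with an estimated correlation). Of the synapse and axon genes 13 of 27 were higher (15 and 1 adjusted over the list alone, camera adjusted p = 9.75e-07, adjusted p = 0.0640 with an estimated correlation). Of genes linked to SCLC 10 of 20 were higher (11 and 1 adjusted over the list alone, camera adjusted p = 0.000242, adjusted p = 0.0234 with an estimated correlation). Chga was higher by 6.23 ± 0.60 and Dll3 by 4.52 ± 0.31 in log2. Mycl was 8.32-fold (log2 change 3.06 ± 0.99, adjusted p = 0.0343) and Sox2 3.64-fold (log2 change 1.87 ± 0.52, adjusted p = 0.0151) higher in limma. Of G2/M genes 29 of 29 were higher (29 adjusted over the list alone, camera adjusted p = 1.36e-27, adjusted p = 0.0640 with an estimated correlation). Of E2F targets 30 of 31 were higher (30 adjusted over the list alone, camera adjusted p = 1.65e-26, adjusted p = 0.0640 with an estimated correlation). Cdkn2a was 49.0-fold, Ccne2 47.9-fold and Mki67 30.4-fold higher. E2f1 had a log2 change of 1.75 ± 0.66 (limma adjusted p = 0.0666). Of homologous recombination and Fanconi genes 12 of 15 were higher (12 adjusted over the list alone, camera adjusted p = 1.57e-09, adjusted p = 0.1001 with an estimated correlation). Of Notch and non-neuroendocrine genes 1 of 20 was higher and 12 lower (1 and 13 adjusted over the list alone, camera adjusted p = 0.000159, adjusted p = 0.175 with an estimated correlation). Notch4 was 7.50-fold lower, and Hes1 had a log2 change of -1.06 ± 0.47 (limma adjusted p = 0.120). As in the Rb/p53 tumours, falls in this list cannot be told apart from a smaller share of lung cells.

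Most lung markers were lower here too. Of endothelial genes 21 of 22 were lower (22 adjusted over the list alone, camera adjusted p = 1.47e-12, adjusted p = 0.134 with an estimated correlation). Of ciliated genes 14 of 19 were lower (14 adjusted over the list alone, camera adjusted p = 2.26e-12, adjusted p = 0.0254 with an estimated correlation). Of alveolar type 1 genes 1 of 14 was higher and 12 lower (1 and 13 adjusted over the list alone, camera adjusted p = 9.87e-05, adjusted p = 0.254 with an estimated correlation). Of alveolar type 2 genes 5 of 15 were lower (7 adjusted over the list alone, camera adjusted p = 0.00536, adjusted p = 0.547 with an estimated correlation), with the protease Napsa 7.12-fold lower. Of club and secretory genes 2 of 13 were lower (2 adjusted over the list alone, camera adjusted p = 0.114), so this list was not called here. Of cardiac muscle genes 13 of 15 were lower (1 and 13 adjusted over the list alone, camera adjusted p = 6.24e-09, adjusted p = 0.0640 with an estimated correlation). Of macrophage and dendritic genes 3 of 19 were higher and 6 lower (5 and 7 adjusted over the list alone, camera adjusted p = 0.277), with the scavenger receptor Marco 8.51-fold lower. In total 5622 of 18193 genes passed in limma, 2775 higher and 2847 lower. Expression did not overlap between the groups in 65.998% of genes, where chance gives 20%. The Gapdh covariate ended the calls of the alveolar type 2, T and NK cell, B and plasma cell and Hedgehog lists, and among genes given for these tumours those of Chga, Elavl2, Klk1, Marco, Mycl, Myh6, Myl7, Napsa, Pcolce2, Ppbp, Rb1, Rbl2, Scg2, Sox2 and Tmem100. With the covariate the log2 change was no smaller for Mycl (4.81) and Rb1 (1.58), but smaller for others, such as Napsa (-1.55) and Marco (-1.76). The count fell to 3650 without normal lung 1 and to 940 with that covariate, and a rank-sum test of 3 against 2 arrays cannot go below 0.2.

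Both tumour genotypes differed from normal lung in much the same genes. Their log2 changes correlated at r = 0.970 across 18193 genes, which are not independent replicates, with a covariance of 1.45. Unchanged groups simulated against the same 2 lungs gave r = 0.707 on average and 0.726 at most, with a covariance of 0.0766. There were 2558 genes higher in both, where independent lists would share 508, and 2730 lower in both, where they would share 584, and 0 went in opposite directions. Both lists of calls use the same 2 lungs, so they are not independent, and their overlap was not simulated. The excess over 508 and 584 may therefore overstate the agreement. With each genotype set against a different normal lung, so that no array was shared, r was 0.922 one way round and 0.912 the other, with a covariance of 1.41 both ways, a test chosen after the data were seen.

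**Figure D2:**
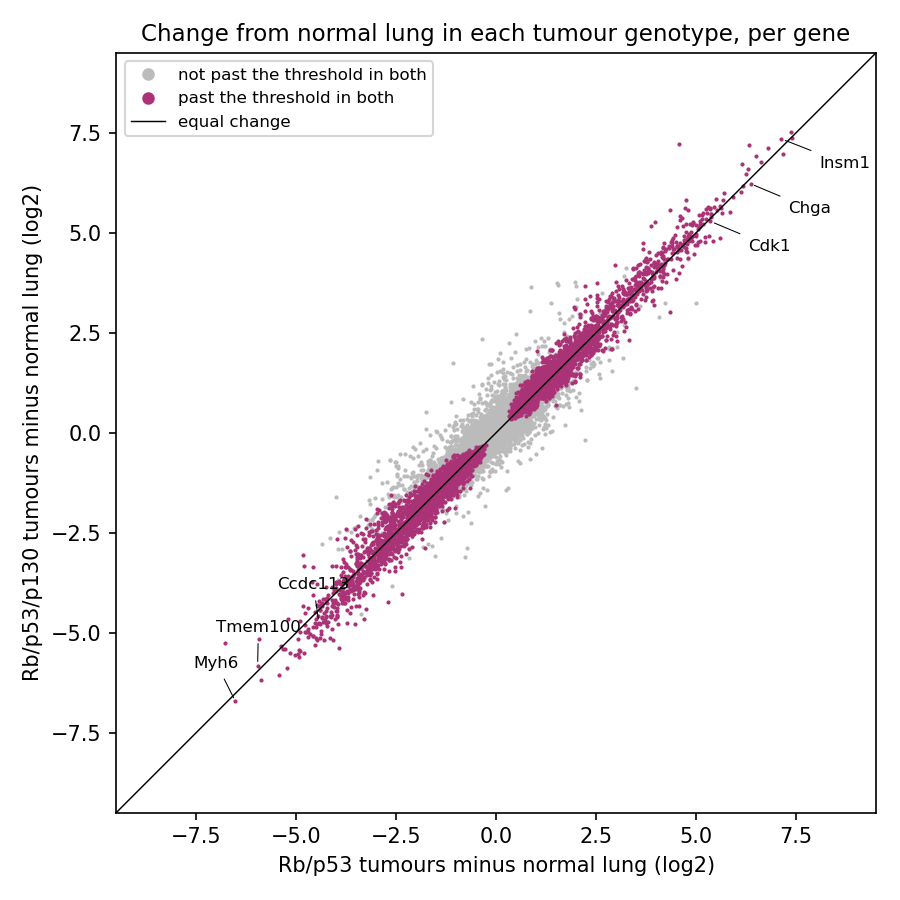
Log2 change from normal lung of each gene in Rb/p53 tumours (horizontal axis) and in Rb/p53/p130 tumours (vertical axis), each point a gene, with the line of equal change. Purple genes passed the threshold in both comparisons and lie along the line, with r = 0.970 over all 18193 genes.

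Rb/p53/p130 tumours were compared with Rb/p53 tumours to ask what the added loss of p130 goes with. Few genes passed the threshold between them. With 3 against 10 arrays this does not show that the rest were equal: simulated changes of 0.5 on the log2 scale were recovered in 9.09% of cases. By the main probe set of each gene, the nuclear RNA Malat1 was 2.95-fold (log2 change -1.56 ± 0.25, adjusted p = 0.0168) lower in the 3 Rb/p53/p130 tumours than in the 10 Rb/p53 tumours, the cohesin loader Mau2 2.55-fold (log2 change -1.35 ± 0.14, adjusted p = 0.000674) lower and the exoribonuclease Xrn2 2.18-fold (log2 change -1.12 ± 0.13, adjusted p = 0.00155) lower (limma, errors are SE). The cytokine signalling inhibitor Socs6 was 1.56-fold (log2 change 0.64 ± 0.08, adjusted p = 0.00432) higher and the helicase-like factor Hltf 1.47-fold (log2 change 0.56 ± 0.10, adjusted p = 0.0266) higher. Arrays of the 2 groups did not overlap for these probe sets. The brightest other probe set was called lower as well for Malat1 (log2 difference -1.80, adjusted p = 0.00583). It was not called for Mau2 (-0.53, adjusted p = 0.0997), Xrn2 (-0.14, 0.881), Socs6 (0.54, 0.402) or Hltf (0.24, 0.776) in limma.

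In all, 13 of 18193 genes passed in limma with Benjamini-Hochberg adjustment, 4 higher and 9 lower, and 1321 had an unadjusted p under 0.05. Expression did not overlap between the groups in 1.97% of genes, where chance gives 0.699%. Vldlr (2.39-fold, log2 change -1.26 ± 0.20), Zbtb7a (2.21-fold, log2 change -1.15 ± 0.17) and Prrc2c (2.15-fold, log2 change -1.11 ± 0.18) were also lower, and Gm10033 (at least 3.01-fold, log2 change 1.59 ± 0.25) and BC023105 (2.71-fold, log2 change 1.44 ± 0.25) higher. The brightest other probe set was not called for Vldlr (-0.50, limma adjusted p = 0.402), Zbtb7a (-0.22, 0.639) or Prrc2c (-0.25, 0.538), although a further probe set of Prrc2c was (-1.66, 0.00968). Among all probe sets 95 passed, 12 higher and 83 lower. These became 17, 19 and 25 without Rb/p53/p130 tumours 11, 12 and 13, 60 and 57 without Rb/p53 tumours 4 and 6, and 150, 160 and 172 without Rb/p53 tumours 1, 3 and 8. Of the 76 called with 1 symbol, 17.1% were the probe set with the highest mean of their gene, against 52.1% of all such probe sets (Fisher's exact test, two-sided p = 4.2e-10). The 52.1% includes genes with a single probe set, which is always their brightest, and the 76 name only 70 genes. The test may therefore overstate the difference. Over the 60 genes with another probe set, the called probe sets had a median log2 change of -1.03 and the brightest other probe set of the same genes one of -0.06 (95% bootstrap interval -0.11 to -0.02). Of these others, 2 were called lower and 40 lay below 0. A probe set of the immunoglobulin gene Ighm, chosen after its values were seen, had a level of 8.09 ± 0.51 (SD) in Rb/p53/p130 tumours, 4.70 ± 0.09 in Rb/p53 tumours and 4.91 ± 0.42 in normal lung (limma adjusted p = 1.47e-07). The main probe set of Ighm stood at 11.66 ± 0.61 and 10.15 ± 1.85 in the tumour groups (SD, limma adjusted p = 0.665).

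**Figure D3:**
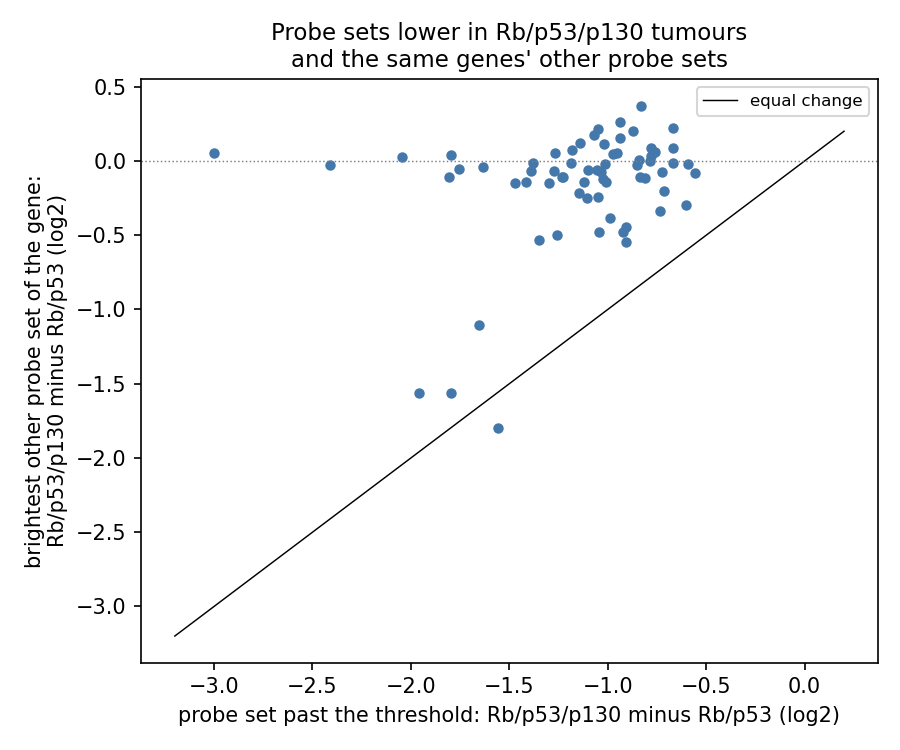
Log2 difference between Rb/p53/p130 and Rb/p53 tumours for the probe sets past the threshold that were lower (horizontal axis, 66 points) and for the brightest other probe set of the same gene (vertical axis), with the line of equal difference and a dotted line at 0. The called probe sets have a median of -1.03 over 60 genes and the others one of -0.06.

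Few neuroendocrine, cell cycle and lung marker genes passed a threshold between the tumour genotypes. No member of any of the 33 lists passed over all genes. Adjusted over the list alone, 1 neuroendocrine and 1 homologous recombination and Fanconi gene were higher, and 1 gene each of the synapse and axon, alveolar type 1, endothelial and adipocyte lists was lower. Insm1 differed by 0.21 ± 0.34, Chga by -0.14 ± 0.43, Mycl by 0.35 ± 0.71, Mki67 by 0.22 ± 0.23 and Cdkn2a by -0.02 ± 0.24, none past the threshold. By camera 6 lists were higher and 5 lower, and 0 of these held with an estimated correlation. Higher by median log2 change were E2F targets (0.16, camera adjusted p = 0.00572, and adjusted p = 0.707 with an estimated correlation) and homologous recombination and Fanconi genes (0.20, camera adjusted p = 0.00498, and adjusted p = 0.667 with an estimated correlation). So were interferon response (0.55, camera adjusted p = 0.00169, and adjusted p = 0.667 with an estimated correlation) and MHC class I presentation (0.36, camera adjusted p = 0.00142, and adjusted p = 0.648 with an estimated correlation). Club and secretory genes (0.75, camera adjusted p = 0.00229, and adjusted p = 0.648 with an estimated correlation) were higher too, but without Rb/p53/p130 tumour 13 the median was 0.25 and not called (camera adjusted p = 0.335). The hepatocyte list was higher (1.39, camera adjusted p = 0.000348, and adjusted p = 0.648 with an estimated correlation), but its mean stood at 9.57 in tumour 12 and its change was -0.16 without that tumour. Lower were hypoxia and glycolysis (-0.34, camera adjusted p = 0.000348, and adjusted p = 0.617 with an estimated correlation) and synapse and axon genes (-0.31, camera adjusted p = 0.000866, and adjusted p = 0.648 with an estimated correlation). Ciliated genes (-0.22, camera adjusted p = 0.00142, and adjusted p = 0.648 with an estimated correlation) were lower, as were fibroblast and smooth muscle genes (-0.31, camera adjusted p = 0.00142, and adjusted p = 0.648 with an estimated correlation). Macrophage and dendritic genes (-0.27, camera adjusted p = 0.0151, and adjusted p = 0.702 with an estimated correlation) were lower as well, but not without Rb/p53/p130 tumour 13 (-0.04, camera adjusted p = 0.589) or Rb/p53 tumour 10 (-0.17, camera adjusted p = 0.122). The E2F target call ended without Rb/p53/p130 tumour 11 (camera adjusted p = 0.0582), Rb/p53 tumour 6 (0.0513) or Rb/p53 tumour 10 (0.0752). All 3 Rb/p53/p130 tumours had high Xist (12.1 to 12.6), as did 5 of the 10 Rb/p53 tumours. Genotype went with time after infection, so the effects of p130 loss and of age cannot be told apart here. The 13 genes became 3 without any 1 of the 3 Rb/p53/p130 tumours (11, 12 or 13) and 21 without Rb/p53 tumour 1. They became 0 with the mean of each gene's probe sets, 662 with array weights and 6 with Xist as a covariate, chosen after the data were seen. An exact rank-sum test gave 0 genes, with 1574 at an unadjusted p under 0.05 and a smallest adjusted p of 0.223.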

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

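All the tests of this part were chosen after the outlying values had been seen; their bounds were set before the tested values were looked at. Each flagged value below is of an Rb/p53 tumour and lay further from the other 9 Rb/p53 tumours than Dixon's 95% limit allows. Chance alone would give about 3.3 such cases among the 66 lists and genes tested, and 8 were found. Rb/p53/p130 tumour 12, given with the hepatocyte list, was not part of this limit test.

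Mycn stood at 12.192 in Rb/p53 tumour 7 against a mean of 7.38 ± 1.02 (SD) in the other 9, and E2f1 at 11.732 in tumour 8 against 8.99 ± 0.26. A single aberrant probe set is argued against, since another probe set of Mycn lay 16.5 SD and another of E2f1 6.20 SD above the other tumours, although a further probe set of each lay only 1.18 and 3.12 SD above. A higher level of the whole chromosomal region is consistent with the neighbouring genes: the mean excess of the 3 nearest measured genes on each side lay at percentile 99.95 of 18017 windows in tumour 7 and 99.88 in tumour 8. Ddx1 (3.28), Nbas (3.66) and Lratd1 (4.31), on 1 side of Mycn, were higher in log2 while Cyria (-0.55) on the other was not, and beside E2f1 1700003F12Rik (4.86), Actl10 (1.71) and Pxmp4 (1.42) were higher while Necab3 (0.03), Zfp341 (0.26) and Gm14198 (-0.06) were close to the other tumours. A gain of DNA copies is a candidate explanation that these arrays do not measure, and of the 4 single genes that stood apart only these 2 were tested in this way.

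The hepatocyte list had a mean of 6.956 in Rb/p53 tumour 2 (other tumours 5.31 ± 0.19, SD), and in the Rb/p53/p130 group tumour 12 reached 9.57. Albumin was at 13.75 in tumour 12 and at 6.16 and 5.35 in the other 2 of its group. Liver RNA in the sample may account for this, but the test was not decisive: 56% of 25 measured genes of a second liver list lay more than 1 above both other tumours, between the bounds of 50% and 80%. Some genes of the second list were already high in the other tumours of the group, such as Hp (13.74 in tumour 13) and Rbp4 (12.65 in tumour 11), which limits this test. Hepatocyte genes switched on in the tumour cells stay open as well, and no biological explanation was tested.

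The other values are given without explanation. Tumour 8 had a synapse and axon mean of 9.607 (others 8.81 ± 0.16, SD) and a tuft-like SCLC mean of 6.633 (others 5.86 ± 0.11). Its Neurod1 level was 6.402 (others 4.51 ± 0.22). Tumour 4 had an adipocyte mean of 6.401 (others 5.74 ± 0.13), and tumour 2 a Cdkn1a level of 12.485 (others 11.49 ± 0.21).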

How the results depend on the processing

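The Xist and actin covariates and the fit without the tumours highest in the hepatocyte list, and the agreement with different lungs, were chosen after seeing the data. The correlation of the genotypes' changes ran from 0.959 to 0.972 with 1 array left out, and was 0.922 and 0.912 with a different lung for each genotype, where a lone lung adds its own noise. Of the genes selected by the fixed rule, not all of which the report names, 50 of 119 for Rb/p53 tumours against normal lung, 41 of 121 for Rb/p53/p130 tumours against normal lung and 50 of 75 between tumour genotypes kept direction and side of the threshold in every setting, as did 11, 7 and 15 of the 33 lists. With 1 array left out, genes past the threshold ran from 4604 to 7194, from 3650 to 5956 and from 3 to 21 in these comparisons, and probe sets between genotypes from 17 to 172. Where a lone normal lung remained, it was assumed to vary like the other groups.

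For Rb/p53 tumours against normal lung, 1106 genes passed with the Gapdh covariate, 4472 with the actin covariate, 4179 with a change of at least 1 and 0 by the exact rank-sum test, whose smallest p was 0.0303. The replicate block gave 3891 genes. Only tumours 1 and 2 share a number with a lung, so that contrast rests on these 2 tumours and the 2 lungs. Deviations of the lungs and tumours numbered 1 and 2 correlated at -0.00426 and -0.0553, which gave no sign of a pairing. The deviations of 2 lungs from their mean mirror each other, so these correlations cannot exclude one. The Gapdh covariate ended the calls of 64 of the 119 genes with the direction kept, of 3 more with it reversed, and of 4 of the 33 lists. For Rb/p53/p130 tumours against normal lung it left 940 genes, ending the calls of 72 of 121 genes and 4 lists. Between genotypes, 0 genes passed with the mean of each gene's probe sets, which averages in fainter ones, and 0 genes and 0 probe sets by the rank-sum test (smallest p 0.00699). Array weights called 662 genes and 2674 probe sets, the Xist covariate 6 and 33, the fit without the tumours highest in the hepatocyte list 5 and 20. Probe sets numbered 151 with the Gapdh covariate, 61 when kept brighter than the median and 57 with a change of at least 1. The Gapdh difference was 0.72 and 0.88 in normal lung and -0.07 to 0.36 in tumours, so it cannot be told apart from tissue. A call lost with it therefore does not show that RNA integrity made the change. The cause was not tested for the covariates and weights.

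Directions reversed in 6 results, and the cause was not tested except where named: the hepatocyte list between genotypes without tumour 12 (-0.16, that tumour alone being high, against 1.97 and 2.07 without tumours 11 and 13); Cd2 (0.76), Ighm (2.08) and Nefm (-1.50) against normal lung in Rb/p53 tumours with the Gapdh covariate, which is confounded with tissue; and Ascl2 (-0.16 in Rb/p53, -0.36 in Rb/p53/p130 tumours) when another probe set stands for the gene. Arrays give no depth; weak probe sets near the lowest values limit small changes.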

Other observations

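The test of a varying share of normal lung was chosen only after its result was seen; those of the lower probe sets were chosen after that pattern was seen, with their bounds set before the tested values were looked at.

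Rb/p53 tumours differed among themselves in lung markers and cell division. Across the 10 tumours the alveolar type 2 list mean fell as the G2/M mean rose (Pearson r = -0.913, permutation p = 0.00054, adjusted p = 0.00144 over 8 relations; Spearman rho = -0.891, p = 0.0011; r = -0.918 without the 2 most extreme tumours). The same mean rose with the endothelial list (r = 0.946, permutation p = 0.00014, adjusted p = 0.0008; rho = 0.952, p = 0.00012; 0.953 without 2). With alveolar type 1 it rose too (r = 0.942, permutation p = 0.0002, adjusted p = 0.0008; rho = 0.903, p = 0.00081; 0.962 without 2). With the ciliated list r was 0.501 (permutation p = 0.14; rho = 0.527, p = 0.12). Interferon response and MHC class I presentation moved together (r = 0.743, permutation p = 0.013, adjusted p = 0.0259; rho = 0.709, p = 0.028, adjusted p = 0.0562), but r was 0.404 without tumours 7 and 5, so the relation rests on them. Interferon response against alveolar type 2 gave r = 0.505 (permutation p = 0.14; rho = 0.455, p = 0.19), and G2/M against neuroendocrine r = -0.474 (permutation p = 0.16; rho = -0.394, p = 0.26).

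A varying share of normal lung in the dissected tissue may lie behind the alveolar and G2/M relation, as a hypothesis. It needs the neuroendocrine list to fall as the alveolar list rises, and r was 0.189 (0.484 without the 2 most extreme tumours; permutation p = 0.59; rho = 0.212, p = 0.56), which decides neither way. The neuroendocrine and G2/M means stood similarly far above normal lung (10.26 against 6.20, and 10.48 against 6.31), so a share of lung should lower both alike. The neuroendocrine mean ran from 9.79 to 10.68 and the G2/M mean from 9.93 to 11.25, and they did not fall together. Tumours may also differ in their own neuroendocrine level, so the share of lung and a difference between tumours were not told apart with these lists.

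The 83 probe sets lower in Rb/p53/p130 than in Rb/p53 tumours had a mean of 7.01 ± 0.05 (SD) and 8.16 ± 0.13, and of 7.28 ± 0.16 in normal lung. Chance division of the 13 tumours is argued against: 2 of 100 splits, the real one included, gave as many genes (13) or probe sets (95), but the highest other, Rb/p53 tumours 7, 8 and 9 against the rest, gave 175 genes and 340 probe sets, which points to a structure among the tumours. A lower level of the whole transcript is argued against for most of these genes, as the brightest other probe set changed by -0.0625 in the median, but single genes were not tested. It stays open for Malat1, whose 7 probe sets all lay lower (-0.39 to -1.96, 3 called). It also stays open for others with more than 1 lower probe set, such as Msi2 (3 called), Prrc2c and Akap13 (2 each), Mau2 (other -0.53) and Phf12 (other -0.55). Of these, Msi2, Akap13 and Phf12 were chosen after their values were seen. RNA integrity as read from actin (median -1.03 with the covariate, 71 of 83 still called) and sex as read from Xist are argued against as the whole cause, although with Xist only 28 of the 83 were still called, with the median change going from -1.05 to -1.0001, the SE rising 1.06 times and fewer calls in all (33 probe sets). Use of other transcript ends or unspliced RNA, p130 loss, tumour age and an unrecorded processing batch stay open, untested, and genotype cannot be told apart from age or batch.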
